A study of Bacillus subtilis with 6 samples.

How the data were processed

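Per the labels, the Bacillus subtilis wild-type strain 168, the common laboratory strain of this soil bacterium, was grown with aeration in LB, a rich medium, at 37 °C. At an optical density of 0.5 the cultures received either argon gas or argon plasma at a discharge power of 5 W, in both cases for 15 min, and cells were collected 5 min later. Argon plasma is the ionised form of the gas, and the gas without discharge is its control. The design text gives 3 biological replicates, so the data hold 6 arrays, 3 per group. Total RNA was obtained by mechanical disruption and acid phenol, and 10 µg per reaction was copied into labelled cDNA with random primers and spike-in RNA, per the labels' protocols. Each sample carried the dye Cy5 and was hybridised against a Cy3-labelled pool made from equal amounts of the RNA of the samples, so that every array shares 1 reference and the reference cancels in a difference between arrays.

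The deposited gene values are linear ratios, 1 per gene and array, for 4105 genes. Per the file headers they are error-weighted averages of the probe ratios of each gene annotated in SubtiList, made with Rosetta Resolver 7.2.1. Image extraction used Agilent Feature Extraction 10.5, per the submitters' processing notes. The normalization within and between arrays, any filter on dim probes and the genome build of the array are not given in the sources used here. The headers also leave open which channel is the numerator. The ratio was taken as sample over pool, the direction that the dye assignment of the labels implies under the usual red over green convention. As a check, the median over the 62 genes called at least 4-fold higher of the log2 mean ratio over all arrays was -0.009 when read as sample over pool and 1.32 when read as pool over sample. A mixture of only these samples would lie at their mean, a log2 value of 0. This check is weak, since 58 genes had a ratio below 0.5 on all 6 arrays, which such a mixture with an unbiased ratio does not give, and the direction rests on the dyes. A second deposited table gives log10 ratios for 41882 numbered probes, with a median of 0 on every array; its unit was read from the values, whose quantiles follow those of the log10 gene ratios. No table used here links these probe numbers to genes, so probe values were only counted and no probe was named.

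The ratios were taken to log2 with no pseudocount and no further normalization. Differences between argon plasma and argon gas were tested for each gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior, 2-sided), with no covariates, on all 6 arrays. P-values were adjusted by the Benjamini-Hochberg method over all 4105 genes, and an adjusted p under 0.05 is what is meant by rose, fell, higher or lower for a gene. Changes are log2(plasma) minus log2(gas), given with the standard error of the fit, which rests on 4 residual and 2.57 prior degrees of freedom. The probe values were tested in the same way after conversion to log2.

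Before the data were examined, 38 gene lists were fixed from regulons, pathways and the marker genes of other cell types that a B. subtilis culture can hold (competent, sporulating, motile and matrix-producing cells). They covered the SOS response, other DNA repair, the prophages PBSX and SPbeta, the mobile element ICEBs1, the peroxide response, organic hydroperoxide and superoxide defence, thiol redox, bacillithiol, quinone and aldehyde response, the CtsR, HrcA, SigB, SigW and SigM/SigX/LiaR stress regulons, cysteine and sulfur supply, methionine S-box genes, iron uptake and other metals. They further covered ribosomal proteins, translation factors with RNA polymerase, purine, pyrimidine, branched-chain amino acid, arginine and histidine with tryptophan synthesis, ribonucleotide reductase, the tricarboxylic acid cycle, glycolysis, respiration, oxygen limitation with nitrate and nitrosative stress, motility, competence, sporulation, biofilm matrix, fatty acid synthesis, compatible solutes with potassium, and exporters. Of the fixed names, 9 were not found. Each list was tested with limma's camera, which asks whether the genes of a list moved together relative to all other genes, with the preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 38 lists. Members past the test were also counted with the adjustment over the list alone. Camera with a correlation estimated from the 6 arrays, and fry, which tests whether the genes of a list move on balance in 1 direction without reference to other genes, were run beside it. When it estimates the correlation, camera also tests on the 4 residual degrees of freedom alone, which lowers its power.

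Genes are named in the text by a rule, fixed at the same time, with 3 parts: the 10 largest rises and 10 largest falls among genes past the test whose groups did not overlap; for each list that camera called, the 3 members with the largest change in the direction of the list and the largest opposite change if it passed the test; and 16 fixed genes whatever their value. Any other gene named was chosen after its value was seen. Symbols are those of the deposited table. The reference gene table of assembly ASM904v1 was used for current symbols. Of the locus tags 4037 matched it and 68 did not, and 1027 symbols differ from the current ones. Neighbours are measured genes next to each other in the order of the deposited locus tags. No coordinates are given because the build of the array is not named.

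The labels number the replicates 1 to 3 in each group without saying what a number shares across groups, so no replicate block was used in the test; the block was run as an alternative. The other alternatives were each array centred on its median, quantile normalization, eBayes with trend and robust fitting, an ordinary test without eBayes, other thresholds, lists without shared genes, and each array left out in turn. After seeing the data, arrays scaled to the same median absolute deviation and limma's array quality weights were added. The planned use of the probe table per gene, and the filter on probes that disagree, needed the missing link from probes to genes and were not run.

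The procedure was tested on simulated data with the spread of the 4105 genes on 3 against 3 arrays. Over 10 simulations it recovered 52.2% of genes changed 2-fold, 85.3% of genes changed 4-fold and 94.2% of genes changed 8-fold, with a mean of 8.1 false calls among 3905 unchanged genes. A list moved 2-fold was called in 10 of 10 simulations, and 2 unchanged lists were called in all; the simulated genes were independent, which real genes are not. The number of arrays limits the precision: the median standard error of a log2 change was 0.206. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.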

Results

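The transcriptome of exponentially growing B. subtilis was compared between cultures that received argon plasma and cultures that received argon gas without discharge, with the purpose of describing the response to physical plasma. Each of the 6 arrays, 3 per group, gave a ratio to the common reference pool for 4105 genes. The ratio was read as sample over pool, from the dyes given in the labels. The median ratio was 0.974, 1.01 and 1.02 on the gas arrays 1 to 3 and 1.004, 1.01 and 0.929 on the plasma arrays 1 to 3. The spread of the log2 ratios over genes was 0.729, 0.696 and 0.713 (SD) on the gas arrays and 0.698, 0.671 and 0.905 on the plasma arrays, with the widest on plasma array 3. Over genes, which are not independent replicates, log2 ratios correlated with r between 0.706 and 0.769 within gas, between 0.530 and 0.739 within plasma and between 0.143 and 0.430 across groups. The first principal component held 55.3% of the variance and separated the groups; the next held 23.2% and set plasma array 2 apart from plasma array 3.

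After argon plasma, 13 of 13 peroxide response genes, 30 of 37 iron uptake genes, 27 of 43 SOS response genes and 9 of 15 thiol redox genes were higher, and 5 of 11 pyrimidine synthesis genes and 7 of 13 tricarboxylic acid cycle genes were lower. These 6 lists were called by camera with its preset correlation, and none of them with a correlation estimated from the arrays (adjusted p from 0.262 to 0.524). The latter test also has less power, as it rests on 4 residual degrees of freedom. The largest rise was that of katA, the vegetative catalase, whose log2 change was 7.68 ± 0.23 (SE, n = 3 arrays per group), a ratio of 205-fold. On each gas array katA had the lowest ratio of all genes (0.0166, 0.0149 and 0.0118). No signal over background is given, so the size of the fold is uncertain. The largest falls were those of mtlD, mannitol-1-phosphate dehydrogenase, at -3.53 ± 0.82, and srfAA, a surfactin synthetase gene, at -3.24 ± 0.32. The call of mtlD ended in 5 of 6 omissions of 1 array, all but that of plasma array 3 (adjusted p of up to 0.132), and after centring (0.0505), quantile normalization (0.0506) or scaling the arrays to 1 spread (0.0576). With limma, 215 genes were higher and 153 lower after plasma, together 8.96% of the 4105 genes, and 164 of the higher and 112 of the lower genes differed at least 2-fold. An unadjusted p under 0.05 was reached by 1084 genes. All 368 called genes had 3 plasma values on 1 side of the 3 gas values; of all genes 1415 did, which is 34.5% against 10% by chance. The median log2 change over all genes was -0.037. The unnamed probes showed 1160 higher and 806 lower of 41882. Of the called genes, 89 higher and 115 lower ones were in none of the fixed lists. The counts fell to 108 higher and 61 lower without gas array 1, to 126 and 58 without gas array 3, and the lower count to 93 without plasma array 1 and 78 without gas array 2. A fit with 1 array left out has less power for every gene. A call that ends in such a fit, here and below, therefore need not mean a smaller change.

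Of the 38 gene lists, 14 were called higher and 8 lower by camera with its preset correlation. With a correlation estimated from the 6 arrays, camera called 0 lists, 5 had an unadjusted p under 0.05, and the adjusted p of the called lists ran from 0.262 to 0.815; fry called 9 of the 22. The loss of calls with the estimated correlation does not rest on the correlation alone. For the quinone and aldehyde list the estimated correlation was 0.0159, near the preset 0.01. Its unadjusted camera p still went from 1.49e-05 to 0.0145. The number of lists called lower was 4 without gas array 1 and 5 without plasma array 2.

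**Figure D1:**
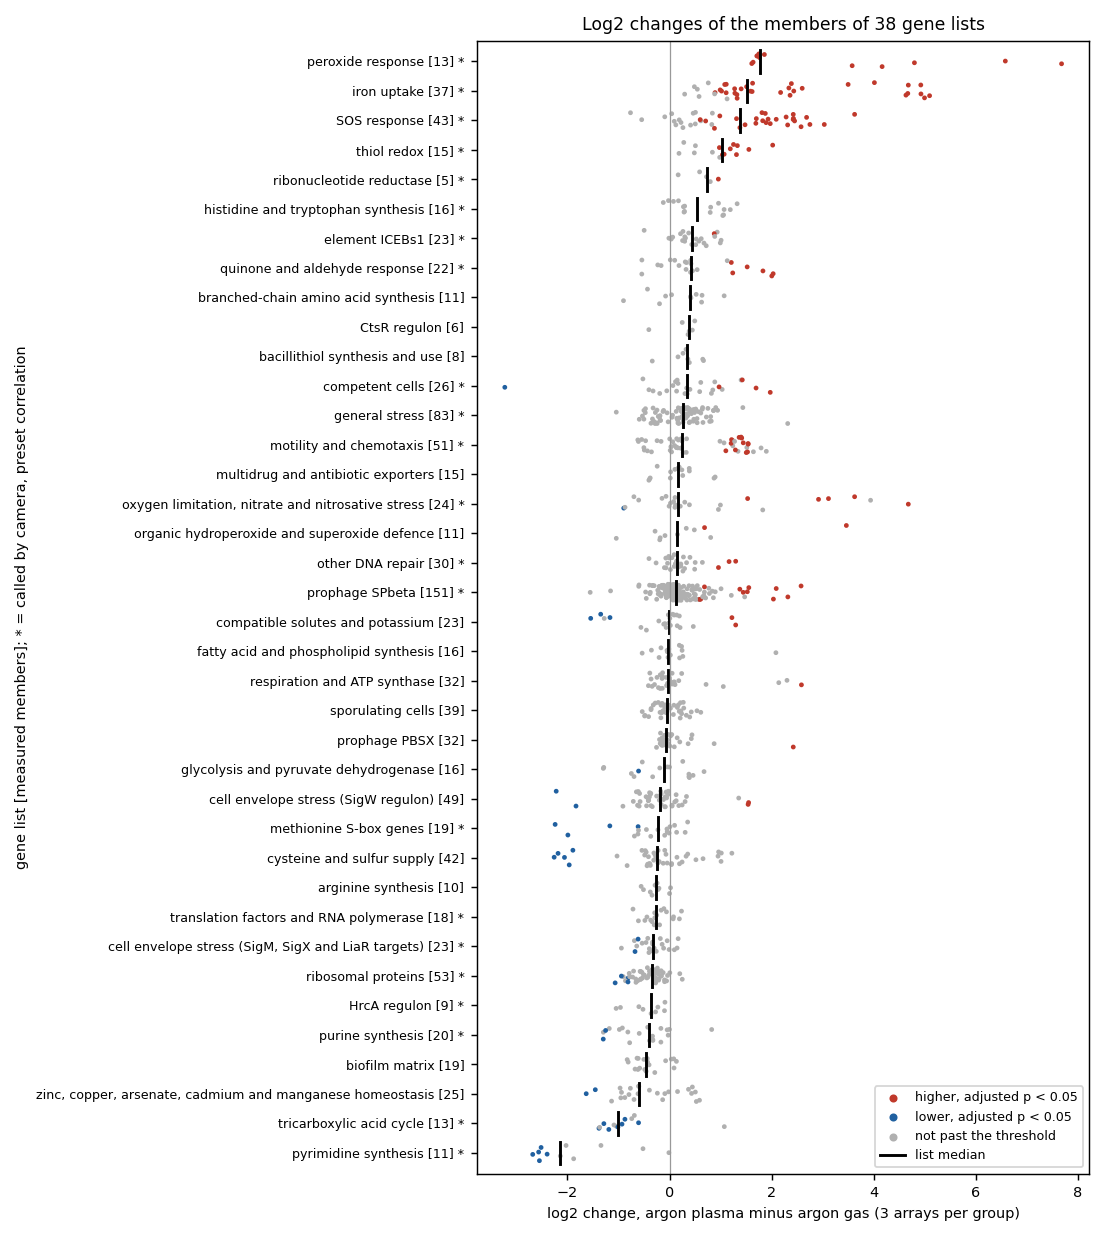
Log2 change (argon plasma minus argon gas, 3 arrays per group, horizontal axis) of the measured members of 38 gene lists (vertical axis, number of members in brackets), with each gene a point, red if higher and blue if lower past the test over all genes and grey otherwise, a black bar at the list median, and an asterisk on lists that camera called with the preset correlation. All 13 peroxide response genes lie at or above 1.61, and the pyrimidine synthesis list has the lowest median, -2.14.

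All 13 measured genes of the peroxide response, controlled by the repressor PerR, rose. After katA the largest rises were those of mrgA, a DNA-binding protein that stores iron, at 6.58 ± 0.48, ykvW, a metal-exporting ATPase listed as pfeT in the reference table, at 4.80 ± 0.38, and the alkyl hydroperoxide reductase gene ahpC at 4.17 ± 0.30. The regulator gene perR itself rose by 1.86 ± 0.14, and the 6 heme synthesis genes from hemA to hemL rose by 1.64 to 1.77. Adjusted over the list alone, 13 were again higher, and the median log2 change was 1.77 (camera adjusted p = 1.81e-16). The adjusted p was 0.262 with an estimated correlation and 0.000776 by fry. In the separate list of organic hydroperoxide and superoxide defence, 2 of 11 genes were higher, also adjusted over the list alone, and the list was not called by camera (adjusted p = 0.183, and adjusted p = 0.509 with an estimated correlation), though fry called it higher (adjusted p = 0.0371). They were yklA, an organic hydroperoxide resistance gene, at 3.46 ± 0.46 and the superoxide dismutase gene sodA at 0.69, both chosen after their values were seen.

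Iron uptake genes, repressed by Fur, were higher in 30 of 37 cases and lower in 0 (36 and 0 adjusted over the list alone). The bacillibactin synthesis genes led: dhbA rose by 5.10 ± 0.26, dhbB by 5.00 ± 0.36, dhbC by 4.93 ± 0.28 and dhbE by 4.92 ± 0.29. The neighbouring genes ykuN, a flavodoxin gene, and ykuO rose by 4.68 ± 0.29 and 4.67 ± 0.29. The list median was 1.51, with the smallest camera p of all lists (adjusted p = 1.78e-31), against an adjusted p = 0.325 with an estimated correlation and 0.00352 by fry. The gene fur, a member of the peroxide list, rose by 1.61.

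The SOS response, the set of DNA damage genes repressed by LexA, had 27 of 43 genes higher and 0 lower, with 30 higher and 2 lower adjusted over the list alone. The gene yolD rose by 3.63 ± 0.25, yneA, an inhibitor of cell division, by 3.03 ± 0.23, and dinB by 2.75 ± 0.26. Of the nucleotide excision repair genes, uvrB rose by 2.69 ± 0.17 and uvrC, outside this list, by 1.17 ± 0.18. The recombinase gene recA rose by 1.97 ± 0.20 and lexA by 1.70 ± 0.19. The list median was 1.38 (camera adjusted p = 3.88e-19, and adjusted p = 0.325 with an estimated correlation, fry adjusted p = 0.00533). Among 30 other DNA repair genes 3 were higher (4 adjusted over the list alone) and 0 lower: uvrC and the end-joining genes ykoV, encoding Ku, at 1.30 ± 0.25 and ykoU, a ligase, at 0.96 ± 0.20. Their median was 0.15 (adjusted p = 0.00733, and adjusted p = 0.325 with an estimated correlation, fry adjusted p = 0.011). The calls of ykoV and ykoU each ended in 5 of 6 omissions of 1 array, all but that of gas array 2, with an adjusted p of up to 0.0951 and 0.124, and that of ykoU also with a replicate block (0.0609).

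Of the 151 listed SPbeta prophage genes, 11 were higher and 0 lower (6 and 0 adjusted over the list alone), led by yorC at 2.58 ± 0.29, yopU at 2.32 ± 0.25 and yorB at 2.09 ± 0.24. The list was fixed by gene names and may not hold every gene of the prophage. The genes yorC and yorB are also SOS list members, and 9 of the 148 SPbeta genes outside that list were higher. The SPbeta list median was 0.13 (adjusted p = 0.00838, and adjusted p = 0.755 with an estimated correlation, fry adjusted p = 0.577). Its call ended without gas array 1 (adjusted p = 0.079), gas array 2 (0.227, median -0.08) or plasma array 3 (0.885, median -0.13), and after scaling the arrays to 1 spread (0.105). Of 23 genes of the integrative element ICEBs1, 1 was higher (yddC at 0.88, chosen after its value was seen) and 0 lower, also adjusted over the list alone. Its largest values, ydcQ at 1.01 ± 0.32, yddE at 0.995 ± 0.24 and ydcR at 0.93 ± 0.37, did not pass (adjusted p between 0.0537 and 0.168); yddE passed without plasma array 1 (0.0253), after quantile normalization (0.0308) and with trend and robust fitting (0.0452). The ICEBs1 list had a median of 0.44 and was called higher (adjusted p = 0.00141, and adjusted p = 0.509 with an estimated correlation, fry adjusted p = 0.106). Of 32 PBSX prophage genes 1 was higher and 0 lower, also adjusted over the list alone; it was xkdA, at 2.42, an SOS list member. The PBSX median was -0.08, the mean 0.08 and the test upward but not past the threshold (adjusted p = 0.635, and adjusted p = 0.923 with an estimated correlation). Without gas array 3 the PBSX list was called higher (median 0.58, adjusted p = 8.53e-07) and without gas array 2 lower (median -0.54, adjusted p = 0.0463). Both calls rest on the preset correlation, while that estimated from the 6 arrays was 0.794 for this list. The PBSX median log2 ratios were -0.818, -1.53 and 0.671 on gas arrays 1 to 3. On plasma arrays 1 to 3 they were -0.338, -0.875 and -0.547.

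Thiol redox genes, most of them activated by the oxidative stress regulator Spx, were higher in 9 of 15 cases and lower in 0 (13 and 0 adjusted over the list alone). The ferredoxin/flavodoxin reductase gene ycgT rose by 2.02 ± 0.17, the NADPH dehydrogenase gene yqjM by 1.56 ± 0.17 and the thioredoxin reductase gene trxB by 1.33 ± 0.25. The gene yjbD, which encodes Spx, had a change of 0.19 ± 0.15 and did not pass (adjusted p = 0.494). The list median was 1.04 (adjusted p = 1.57e-09, and adjusted p = 0.325 with an estimated correlation, fry adjusted p = 0.00805). In the quinone and aldehyde response, 6 of 22 genes were higher and 0 lower (7 and 0 adjusted over the list alone), including yodD at 2.03 ± 0.22, yodE, a dioxygenase gene, at 2.00 ± 0.17 and yvaB, an azoreductase gene, at 1.83 ± 0.26. The median was 0.41 (adjusted p = 8.09e-05, and adjusted p = 0.275 with an estimated correlation, fry adjusted p = 0.00429). Bacillithiol genes had 0 of 8 past the limma test over all genes and 2 higher adjusted over the list alone (2 with an unadjusted p under 0.05). The list missed the threshold (median 0.34, adjusted p = 0.0504, and adjusted p = 0.524 with an estimated correlation). With all 6 arrays it was called after centring each array (0.0381), with trend and robust fitting (0.031) and without genes of other lists (0.0208). With 1 array left out it was called without gas array 3 (0.0436) and without plasma array 3 (0.016). The call of trxB ended without gas array 1 or 2 or plasma array 1 or 2, with an adjusted p of up to 0.0875.

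**Figure D2:**
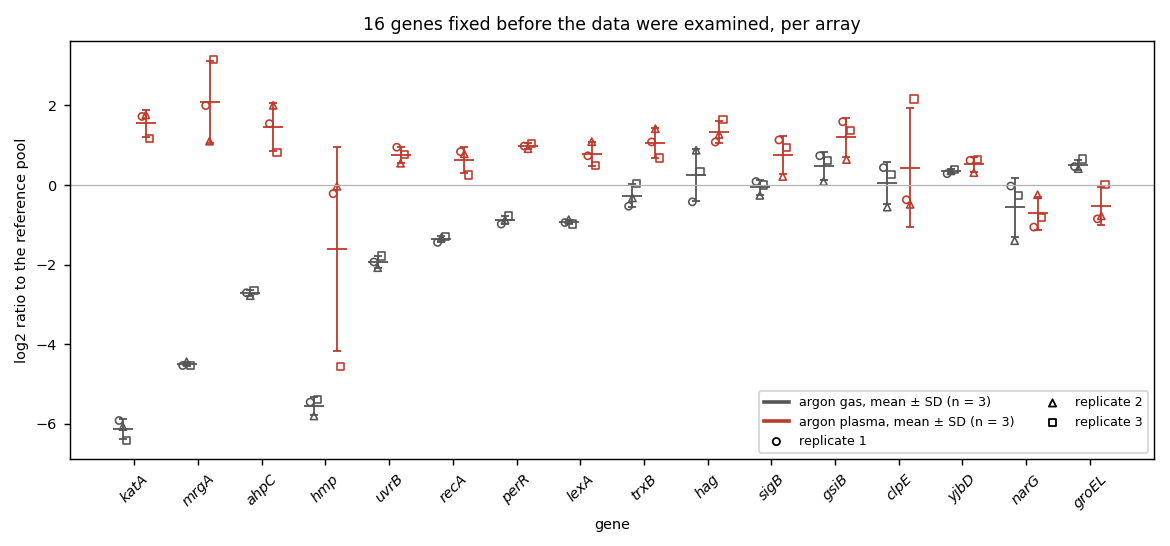
Log2 ratio to the reference pool (vertical axis) of the 16 genes that were fixed in advance (horizontal axis); each symbol is 1 array, its shape giving the replicate, grey for argon gas and red for argon plasma, and lines and bars are the mean and SD of 3 arrays. The katA mean lies at 1.55 after plasma and -6.13 after gas, and hmp on plasma array 3 lies at -4.56, beside the gas arrays.

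In the list for oxygen limitation, nitrate and nitrosative stress, 5 of 24 genes were higher and 1 lower (7 and 2 adjusted over the list alone). The list median was 0.16 (adjusted p = 0.0142, and adjusted p = 0.563 with an estimated correlation, fry adjusted p = 0.186). The higher genes were ykuN, already counted with iron uptake, the lactate genes lctP (a permease, 3.63 ± 0.75) and ldh (lactate dehydrogenase, 3.11), and the nitrite reductase genes nasD (2.92 ± 0.43) and nasE (1.53 ± 0.32). Of these, ldh, nasD and nasE were chosen after their values were seen. The nitrate reductase gene nasC fell by 0.90 ± 0.19. The flavohaemoglobin gene hmp, which detoxifies nitric oxide, had a change of 3.94 ± 1.17 and did not pass (adjusted p = 0.0899). On plasma arrays 1 and 2 hmp lay at -0.22 and -0.03 against -5.80 to -5.38 on the gas arrays, and without plasma array 3 its change was 5.42 ± 0.18 (adjusted p = 0.000759; up to 0.233 without another array). It also passed after scaling the arrays to 1 spread (5.48, adjusted p = 0.0145). The respiratory nitrate reductase gene narG had a change of -0.15 ± 0.40 (adjusted p = 0.863), a sign that turned after scaling the arrays to 1 spread (0.15) and without gas array 1, plasma array 1 or gas array 3. The list was not called without gas array 2 (adjusted p = 0.154) or plasma array 2 (0.0783), and its median ran from 0.093 to 0.515 with 1 array left out. The call of lctP ended without gas array 1, 2 or 3 or plasma array 2 and that of nasC in 5 of 6 omissions, all but that of plasma array 2 (adjusted p of up to 0.105 and 0.12). Of 32 respiration and ATP synthase genes 1 was higher, cydD at 2.59, chosen after its value was seen, and 0 lower; adjusted over the list alone 0 passed. The genes cydB (2.30), cydC (2.14) and cydA (1.05), chosen in the same way, changed in the same direction. They did not pass limma (adjusted p of 0.0616, 0.0611 and 0.2). That list had a median of -0.03, a mean of 0.20 and an upward test that was not past the threshold (adjusted p = 0.707), but was after scaling the arrays (0.000203, median 0.23).

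Motility genes rose in part: 13 of 51 motility and chemotaxis genes were higher and 0 lower (22 and 6 adjusted over the list alone). The motility median was 0.24 (adjusted p = 1.38e-04, and adjusted p = 0.563 with an estimated correlation, fry adjusted p = 0.119). The chemoreceptor gene mcpA (1.90 ± 0.49) and the flagellar motor genes motA (1.79 ± 0.52) and motB (1.64 ± 0.48) had the largest changes and did not pass (adjusted p of 0.0621, 0.0882 and 0.0893). They passed without gas array 2 (0.0323, 0.0333 and 0.0323) and with a replicate block (0.0207, 0.0343 and 0.0362). The flagellin gene hag had a change of 1.07 ± 0.34 and did not pass (adjusted p = 0.108). Genes past the test included fliT at 1.54 and the autolysin gene lytF at 1.36, both chosen after their values were seen. In the list of competent cells, 4 of 26 genes were higher and 1 lower (8 and 2 adjusted over the list alone). The median in this list was 0.34 (adjusted p = 0.00332, and adjusted p = 0.509 with an estimated correlation, fry adjusted p = 0.0743). Besides recA, which is shared with the SOS list, these were the DNA uptake genes comGA (1.70 ± 0.36), comGB (1.43 ± 0.31) and comFA (0.97, chosen after its value was seen). The lower gene was comS at -3.23 ± 0.30, a competence activator that lies inside the surfactin synthetase operon and fell by about as much as srfAA. The calls of comGA and comGB each ended in 5 of 6 omissions of 1 array, all but that of plasma array 1 (adjusted p of up to 0.112 and 0.13), and that of comGB also with a replicate block (0.0553).

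Of the 39 sporulation genes and the 19 biofilm matrix genes, 0 passed limma, both over all genes and adjusted over the list alone, and 2 and 1 had an unadjusted p under 0.05. The sporulation list had a median of -0.05 (adjusted p = 0.845, and adjusted p = 0.923 with an estimated correlation). The biofilm list had a median of -0.46 (adjusted p = 0.0596, and adjusted p = 0.755 with an estimated correlation) and was called lower without plasma array 1 (0.000814) or gas array 3 (0.002), with a replicate block (0.0169) and after quantile normalization (0.0204), while its median was 0.10 after scaling the arrays (adjusted p = 0.50). Fry gave adjusted p-values of 0.442 and 0.498.

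The general stress list, the SigB regulon, held 83 genes, of which 0 were past limma over all genes or adjusted over the list alone and 11 had an unadjusted p under 0.05. Camera called it higher with a median of 0.26 (adjusted p = 0.0137, and adjusted p = 0.815 with an estimated correlation, fry adjusted p = 0.732). Its largest upward changes were yvyD at 2.32 ± 0.70, a ribosome hibernation gene listed as hpf, yflT at 1.44 ± 0.50 and ywzA at 0.94 ± 0.51, with sigB at 0.82 ± 0.26 and gsiB at 0.72 ± 0.30 (adjusted p between 0.0943 and 0.297). The largest downward one was katX at -1.04 (adjusted p = 0.107), chosen after its value was seen. The list was not called without plasma array 1 (0.557), gas array 2 (0.112) or plasma array 3 (0.281), nor after quantile normalization (0.221) or scaling to 1 spread (0.507). Its median ran from 0.07 to 0.59 with 1 array left out. Without plasma array 2, yflT, ywzA and sigB passed (0.027, 0.023 and 0.027), as did yvyD without plasma array 3 (0.0169) and yflT with a replicate block (0.0403). Chaperone genes of the HrcA regulon had 0 of 9 past limma over all genes and 1 lower adjusted over the list alone (3 with an unadjusted p under 0.05). The HrcA median was -0.36 (adjusted p = 0.0299, and adjusted p = 0.658 with an estimated correlation, fry adjusted p = 0.228). The values were -1.05 ± 0.26 for groEL (adjusted p = 0.0543), -0.96 ± 0.33 for groES and -0.60 ± 0.24 for grpE. Without plasma array 3 groEL and groES passed (0.00656 and 0.0151), and groEL also with a replicate block (0.0437), after quantile normalization (0.0498) and with trend and robust fitting (0.0466). The HrcA list call ended without gas array 1 (0.067), plasma array 1 (0.176), plasma array 2 (0.152) or gas array 3 (0.0531). Its median ran from -0.609 to -0.25 with 1 array left out. The Clp protease genes of the CtsR regulon had 0 of 6 past limma, also adjusted over the list alone, and 1 with an unadjusted p under 0.05 (median 0.37, adjusted p = 0.653, and adjusted p = 0.923 with an estimated correlation, fry adjusted p = 0.865). Its median log2 ratio on plasma array 3 was 1.37, against 0.29 and -0.16 on the other plasma arrays. For clpE the change was 0.39 ± 0.72 (adjusted p = 0.787), and -0.48 without plasma array 3.

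The list of SigM, SigX and LiaR targets, which respond to envelope stress, had 0 of 23 genes higher and 2 lower (0 and 0 adjusted over the list alone). Their median change was -0.33 (adjusted p = 0.00448, and adjusted p = 0.562 with an estimated correlation, fry adjusted p = 0.0993). The sigma factor gene sigM fell by 0.68 ± 0.16 (adjusted p = 0.0498), a call that ended in 6 of 6 omissions (0.0714 to 0.173), with a replicate block (0.0692) and with trend and robust fitting (0.0644). Further, rodA, a cell shape gene chosen after its value was seen, fell by 0.62. The genes ywoA (-0.94 ± 0.26), an undecaprenyl pyrophosphate phosphatase gene, and yfnI (-0.69 ± 0.29), a lipoteichoic acid synthase gene, did not pass, but yfnI did without plasma array 2 (0.0493) and ywoA after quantile normalization (0.0323). The list call ended without gas array 1 (0.07) or plasma array 2 (0.052) or with array quality weights (0.0893). In the SigW regulon 2 of 49 genes were higher and 2 lower (3 and 2 adjusted over the list alone), namely yuaI (1.54), yuaG (1.55), yrhH (-2.22) and yrhJ (-1.83), chosen after their values were seen. That list was not called (median -0.18, adjusted p = 0.34, and adjusted p = 0.923 with an estimated correlation), but was called lower without plasma array 1 (0.0417) or plasma array 3 (0.0169) and after quantile normalization (0.0129) or scaling (0.000825), while its median was 0.145 without plasma array 2.

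Pyrimidine synthesis had the largest median fall of all lists, -2.14, with 5 of 11 genes lower and 0 higher (6 and 0 adjusted over the list alone). The genes pyrD, pyrF, pyrE and pyrK fell, with changes of -2.68 ± 0.48, -2.56 ± 0.46, -2.55 ± 0.48 and -2.52 ± 0.46. The list was called at an adjusted p of 1.60e-04, with an adjusted p = 0.524 with an estimated correlation and 0.0993 by fry. Purine synthesis had 2 of 20 genes lower and 0 higher, also adjusted over the list alone: purH at -1.30 ± 0.30 and purD at -1.25 ± 0.29, while purN at -1.30 ± 0.41 did not pass, but did with a replicate block (0.017). Its median was -0.41 (adjusted p = 0.0269, and adjusted p = 0.727 with an estimated correlation, fry adjusted p = 0.384). The list for ribonucleotide reductase, which makes deoxyribonucleotides, held 5 genes, not all of which encode the enzyme. Of these 5 genes, 1 was higher (2 adjusted over the list alone) and 0 were lower. They had a median of 0.73 (adjusted p = 0.0137, and adjusted p = 0.507 with an estimated correlation, fry adjusted p = 0.0613), and ymaB rose by 0.96 ± 0.21 while nrdF (0.80 ± 0.26) and nrdE (0.73 ± 0.27) did not pass. Without plasma array 3 nrdF and nrdE passed (0.0237 and 0.0288). The purine list was not called without gas array 1 (0.317), plasma array 1 (0.0776) or plasma array 2 (0.284), nor after scaling the arrays to 1 spread (0.0786). Its median ran from -0.925 to -0.172 with 1 array left out. The calls of pyrD, pyrF, pyrE and pyrK ended without gas array 1 or gas array 3, those of pyrD, pyrE and pyrK also without plasma array 1, and that of pyrE also without gas array 2 (adjusted p of up to 0.0711, 0.0775, 0.092 and 0.0858). Those of purH and purD each ended in 5 of 6 omissions, all but that of plasma array 1, and after centring the arrays (up to 0.151 and 0.149). The call of purH also ended after quantile normalization (0.0568) and scaling (0.054), and that of ymaB in all but that of plasma array 3 (up to 0.135) and with a replicate block (0.0727).

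The tricarboxylic acid cycle list had 7 of 13 genes lower and 0 higher (12 and 0 adjusted over the list alone). The median change was -1.01 (adjusted p = 1.46e-05, and adjusted p = 0.507 with an estimated correlation, fry adjusted p = 0.0371). The succinate dehydrogenase gene sdhA fell by 1.38 ± 0.29 and the citrate synthase gene citZ had a change of -1.29 ± 0.22, while sdhC at -1.37 ± 0.39 did not pass (adjusted p = 0.085, and 0.0409 after quantile normalization). The call of citZ ended without gas array 3 (0.0666) and that of sdhA in 5 of 6 omissions, all but that of plasma array 2 (up to 0.116). Of 16 genes of glycolysis and pyruvate dehydrogenase, 0 were higher and 1 was lower (4 adjusted over the list alone). The gene was pdhD, also counted in the cycle. Camera did not call the list (median -0.12, adjusted p = 0.303, and adjusted p = 0.524 with an estimated correlation), though fry called it lower (adjusted p = 0.0371).

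Ribosomal protein genes had 4 of 53 lower and 0 higher (9 and 0 adjusted over the list alone), and 50 of the 53 had a negative change. Their median was -0.34 (adjusted p = 1.46e-05, and adjusted p = 0.524 with an estimated correlation, fry adjusted p = 0.0993). The median log2 ratio of these genes was 0.222, 0.307 and 0.204 on gas arrays 1 to 3. On plasma arrays 1 to 3 it was -0.294, 0.193 and -0.453, so plasma array 2 lay near the gas arrays. The genes rpmA and rplU fell, with changes of -1.06 ± 0.14 and -0.94 ± 0.15, and rpsH at -0.91 ± 0.31 did not pass. Translation factors and RNA polymerase had 0 of 18 past limma, also adjusted over the list alone (3 with an unadjusted p under 0.05). The median was -0.27 (adjusted p = 0.0337, and adjusted p = 0.507 with an estimated correlation, fry adjusted p = 0.0371). Their largest values were infA at -0.72 ± 0.24, infC at -0.61 ± 0.15 (adjusted p = 0.0509, and 0.0489 after centring the arrays) and rpoA at -0.48 ± 0.21. The call of the latter list ended without gas array 1 (0.0846) or plasma array 1 (0.136), with a replicate block (0.0578) or after quantile normalization (0.0663). The call of rplU ended without gas array 1, plasma array 1 or gas array 3 (up to 0.0687). Conversely, infA and rpsH passed without plasma array 2 (0.0455 and 0.0182).

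Among amino acid and sulfur genes, 4 of 19 methionine S-box genes were lower and 0 higher (7 and 0 adjusted over the list alone). The S-box median was -0.23 (adjusted p = 0.0118, and adjusted p = 0.507 with an estimated correlation, fry adjusted p = 0.0371). The lower genes included the methionine salvage genes ykrT, ykrS and ykrW, with changes of -2.24 ± 0.26, -1.99 ± 0.27 and -1.17 ± 0.17. The histidine and tryptophan list had 0 of 16 genes past limma, also adjusted over the list alone (4 with an unadjusted p under 0.05). Camera called it higher with a median of 0.55 (adjusted p = 0.00448, and adjusted p = 0.524 with an estimated correlation, fry adjusted p = 0.192). Its largest values were hisI at 1.33 ± 0.41, hisB at 1.19 ± 0.48 and hisA at 1.07 ± 0.40, each of which passed without plasma array 1 (0.0209, 0.0482 and 0.0343). The list was not called after quantile normalization (0.281) or with array quality weights (0.0841). Its genes trpE, trpD, trpC, trpF and trpB had log2 ratios between -5.49 and -3.83 on all 6 arrays. No signal over background is given, so their small changes are uncertain. In cysteine and sulfur supply, 0 of 42 genes were higher and 5 lower (2 and 6 adjusted over the list alone). The lower ones were the sulfate assimilation genes sat (-2.26), cysC (-2.18), ylnD (-2.06), cysH (-1.96) and cysP (-1.89), chosen after their values were seen, which lie next to the pyr genes. The list was not called (median -0.25, adjusted p = 0.462, and adjusted p = 0.923 with an estimated correlation), but was called lower without gas array 3 (0.0301), while its median was 0.345 without gas array 1 and 0.235 after scaling. Of 10 arginine and 11 branched-chain amino acid synthesis genes, 0 were past limma, also adjusted over the list alone (0 and 1 with an unadjusted p under 0.05). The medians were -0.26 (adjusted p = 0.104, fry adjusted p = 0.267) and 0.41 (adjusted p = 0.653, fry adjusted p = 0.865). The branched-chain median was -0.158 without plasma array 2. Arginine synthesis was called lower without gas array 3 (0.0283).

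The remaining lists were not called by camera. Of 25 zinc, copper, arsenate, cadmium and manganese genes, 0 were higher and 2 lower (2 and 6 adjusted over the list alone), the copper export genes yvgX (-1.63) and yvgY (-1.45), chosen after their values were seen. The median was -0.60 (adjusted p = 0.0778, and adjusted p = 0.507 with an estimated correlation, fry adjusted p = 0.025). Without gas array 3 (0.0303) and with a replicate block (0.0184) the list was called lower. Of 23 genes for compatible solutes and potassium, 2 were higher, the proline synthesis genes proH (1.30) and proJ (1.22), and 3 were lower, the osmolyte uptake genes opuCB (-1.17), opuCC (-1.35) and opuCD (-1.54), again chosen after their values were seen. Adjusted over the list alone the counts were 2 and 4, and the median was -0.02 (adjusted p = 0.617). Of 16 genes for fatty acid and phospholipid synthesis and 15 exporter genes, 0 were past limma, also adjusted over the list alone (0 and 3 with an unadjusted p under 0.05). The former list had a median of -0.02, a mean of 0.11 and a downward test (adjusted p = 0.90, fry adjusted p = 0.923), and was called lower without plasma array 3 (0.0351). The exporter median was 0.16 (adjusted p = 0.369, fry adjusted p = 0.203).

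Outside the lists, yobU rose by 5.69 ± 0.21, the third largest rise. Large falls were those of ycdA at -3.19 ± 0.29, the ammonium transporter gene nrgA at -2.85 ± 0.55 and yxiC at -2.50 ± 0.29. The call of nrgA ended in 5 of 6 omissions of 1 array, all but that of gas array 2 (adjusted p of up to 0.0943). Its change ran from -3.46 to -2.37 over the 6 omissions. The calls of katA, mrgA, yobU, ycdA, comS and srfAA held under every alternative run for single genes, which leaves out the ordinary test and the other thresholds.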

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

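Of the 55 named genes past the test, 48 stayed past it under every alternative run for single genes that kept 6 arrays. With each array left out as well, 35 stayed. The ordinary test without eBayes and the other thresholds were not scored for single genes. Over all genes, that ordinary test kept 104 of the 215 higher and 43 of the 153 lower calls. Of the 22 called lists, 14 stayed called under every alternative other than the estimated correlation and fry. The array quality weights and the scaling of arrays to 1 spread were chosen after seeing the data. Higher and lower genes numbered 496 and 423 with array quality weights, which gave plasma array 3 a weight of 0.239 and plasma array 1 one of 3.61 (the fit of the weights stopped before it converged), 113 and 50 in the ordinary test without eBayes, and 100 and 39 at an adjusted p under 0.01, where a stricter limit is the reason; the cause of the other shifts was not tested. With 1 array left out, the counts ran from 108 to 216 higher and from 58 to 119 lower, with fewer samples in each fit, and the lists from 11 to 16 higher and from 4 to 11 lower. Lists called higher and lower numbered 0 and 0 with the estimated correlation, and 7 and 5 by fry. Centring gave 256 and 158 genes, quantile normalization 251 and 182, scaling 261 and 161, and trend with robust fitting 222 and 155. The sign turned for narG with scaling (0.15) and with 1 array left out (from -0.57 to 0.12 over the 6 omissions, turned values 0.12, 0.028 and 0.0046), for clpE with array quality weights (-0.30) and without plasma array 3 (-0.48; range -0.48 to 0.85), for the test of the SPbeta list with array quality weights (median -0.28, adjusted p = 0.755), and for the test of the PBSX list without gas array 2 (median -0.54; range -0.54 to 0.58); the cause was not tested. The median of a list, apart from its test, turned under some alternative for 12 of 38 lists, of which SPbeta was the only 1 called (also -0.084 without gas array 2 and -0.128 without plasma array 3). Same-numbered gas and plasma arrays deviated from their group means with correlations of -0.094, 0.393 and 0.126 over genes, and gas array 1 deviated most like plasma array 3 (0.308), so not every array went best with its own number; with the replicate block 207 genes were higher and 145 lower, and 14 and 9 lists. Of the 32 named genes not past the test, 20 passed with array quality weights, 6 after scaling and 6 after quantile normalization. The per-gene use of the probe table, its mean over probes and the filter on disagreeing probes were not run, for want of a link from probes to genes. No signal over background is given in the tables used here, so dim genes could not be set apart.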

Other observations

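The tests of neighbouring genes, of the reference pool and of plasma array 3 below were chosen only after the values were seen; the test on other phosphate genes and the regrouping of the arrays were written down before their results, though how the spread of the phosphate test was measured was chosen after its value was seen. Among called genes outside the fixed lists, several operons moved as a block. The 8 tua genes for teichuronic acid, a phosphate-free cell wall polymer, rose by 2.52 to 3.47, and the 5 genes of the pst phosphate transporter rose by 1.73 to 2.82. The 5 iron-sulfur cluster assembly genes from yurU to yurY rose by 1.30 to 1.67. Over all called genes, those of the lists included, 22 runs of at least 4 neighbouring genes were called the same way, 13 higher and 9 lower. They held 131 genes, of which 57 were in fixed lists, and 9 runs held none of these.

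Lower runs were found for the surfactin operon from srfAA to srfAC (4 genes with comS, -3.24 to -2.18), for 7 genes from ycsF to ycsK (-1.80 to -1.60), which include kipI and kipA, an inhibitor of a sporulation kinase and its antagonist, and for 8 genes from yueD to yukE (-2.48 to -1.04), most of them for a secretion system. Further lower runs were 11 genes from deaD, an RNA helicase gene, to yxiF (-1.34 to -0.67), 5 genes from yxxE to yxiB (-2.50 to -1.25) and 6 genes from yfjF to yfjA (-2.00 to -0.93).

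In phosphate starvation PhoP activates both tua and pst, so a PhoP response was tested on 7 other PhoP-activated genes. Their median log2 change was -0.064, with 1 of 7 past the test (phoB, 2.03 ± 0.18, with phoP at -0.07 ± 0.24, phoR at -0.10 ± 0.20 and glpQ at 1.30 ± 0.70), and the PhoP-repressed tag genes had a median of 0.10. The median lay below the bound of 0.5 set beforehand, at -0.15 to 0.098 with each array left out, and 4 of the 7 genes lay more than 2 standard errors below it. By that bound the 7 genes did not rise as a set. Their changes were uneven, however, and the way to measure their spread was chosen after the value was seen. The test therefore does not decide whether PhoP caused the rise of tua and pst. The gene phoB rose with these operons. The difference between groups of the medians per array, a measure on which no bound was set, was 0.26 with a standard error of 0.189. The value 2 standard errors above it (0.637) is past 0.5. The 7 changes had an SD of 0.898, and their median lay further than that below the smallest rise of a pst gene. Whether PhoP raised these operons stays open, and regulation by other means was not tested.

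A pool of equal parts of these 6 RNAs should lie between its parts, yet 58 genes had a ratio below 0.5 on all 6 arrays, against 2 genes with a ratio above 2 on all of them. The trpE, trpD, trpC, trpF and trpB genes lay between -5.49 and -3.83 (log2), cydA between -5.00 and -2.70, and 12 of the 19 biofilm genes were in the set. It also held hxlA, hxlB, ydfN and ydfO of the quinone and aldehyde list. A set of 58 genes argues against a pool that held only RNA of these samples with an unbiased ratio. Of the 58 genes, 45 had a neighbour in the set, against 4 at the 95th percentile and 8 at most in 1000 random draws, which argues against a dye bias of single probe sequences. RNA of other cultures in the pool and a bias that depends on intensity may each give such ratios and stay open; both cancel in the difference between groups where they act alike on all arrays.

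The nitric oxide response genes hmp and ykjA of plasma array 3 lay at -4.56 and -4.52, near the gas arrays, while plasma arrays 1 and 2 lay at -0.22 and -0.03 for hmp and at -1.72 and -1.57 for ykjA. An exchange with a gas array is argued against by the peroxide genes, of which 13 of 13 on plasma array 3 lay above all gas arrays. The wider spread of that array was tested by scaling, after which hmp still lay at -2.82 and ykjA at -1.31 relative to the mean of plasma arrays 1 and 2. Over 267 genes at least 2-fold higher on plasma arrays 1 and 2 than on gas, the median gap to that mean was -0.269. The gap of katA was -0.843 and that of nasE -0.895. These genes were chosen for high values on plasma arrays 1 and 2, so a lower value on plasma array 3 is partly built in. The gap of hmp was the lowest of all 267. Its low value on plasma array 3 had prompted the test, so this rank does not decide whether the spread is its whole cause. For ykjA, 10 of the 267 genes, itself included, had a gap at least as low, so its value cannot be told apart from those of other genes chosen in this way. Both gaps shrank with scaling, from -4.44 and -2.87, and hmp passed the test after it (5.48, adjusted p = 0.0145). Scaling by construction pulls in every low value of the array with the widest spread. These results therefore do not decide whether the spread accounts for a part of the pattern. A biological difference between the plasma cultures was not tested and stays open. The genes yvyD and clpE each lay higher on plasma array 3 than on any other array, at 2.43 and 2.16.

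Of the 10 ways to split the 6 arrays into 3 and 3, only 1, the real one, gave as many genes as the 368 called, and the highest of the others gave 0. Every other split put gas and plasma arrays into the same group, which widens the spread where gas and plasma differ. The count of 0 is therefore partly built in. With 10 splits the share cannot be under 0.1, so the splits are too few to exclude chance.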
